A study of Rattus norvegicus with 24 samples.

How the data were processed

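RNA-seq and ribosome profiling (sequencing of the mRNA pieces protected by ribosomes) were measured in brain and liver of 3 young rats aged 6 months and 3 old rats aged 24 months, which gives 8 groups of 3 libraries and 24 libraries. Each deposited file held whole-number counts for the same 22938 transcripts in one library, not normalised, beside a length-like value that no header defines. RNA-seq libraries were made with a stranded kit from total RNA, and ribosome profiling libraries from RNase I footprints of pelleted ribosomes by linker ligation, reverse transcription, circularisation and PCR, per the labels' protocols. The submitters' processing notes name Bowtie 1.0.0.0, TopHat2 2.0.10, DESeq and the rat genome build rn4. Which step used which tool, the annotation, the counting rule, the treatment of reads that map to several places and any removal of duplicates are not given in the sources used here. Transcripts of one gene can share reads under some counting rules, so single transcripts with near-identical copies are uncertain. Among the 22938 transcripts, 4960 had 0 counts in all libraries, and 41 of those with a total of at least 50 counts had the same counts in every library as another one. The length-like value ran from -17 to 8007 with a median of 349 and was missing for 3097 transcripts, which held 0 counts. It entered only the checks of a length trend.

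The count tables give transcript identifiers alone. A table of rat genes of assembly GRCr8 was searched on every identifier column, and 0 of the 22938 identifiers matched, so no gene names are used. The 47 gene lists fixed beforehand, their set tests and the panel of single genes therefore could not be run, and the alternative that leaves mitochondrially encoded genes out of the library sizes left out only the 10 most abundant transcripts. The transcripts named in the text follow a rule fixed before the data were examined, without its condition on gene symbols. They had an adjusted p under 0.05, an average log2 CPM of at least 0 and, for comparisons of ages within one assay, no overlap between the 3 old and the 3 young libraries. Of these the 2 with the largest rise and the 2 with the largest fall were taken per comparison, where there were as many. That limit to 2 was set after the identifiers were found to have no names.

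Totals ranged from 14281043 to 28664906 counts in RNA-seq and from 5259326 to 17584871 in ribosome profiling. Replicates correlated across transcripts at 0.983 to 0.994 in brain RNA-seq, 0.952 to 0.976 in brain ribosome profiling, 0.965 to 0.991 in liver RNA-seq and 0.947 to 0.984 in liver ribosome profiling (Pearson's r of log2 CPM), and no replicate pair agreed to within counting noise (chi-square per degree of freedom at least 3.27). Counts come from PCR reads without molecular identifiers, so floors and counting intervals cover counting error only. A transcript with 0 counts in a group was set against a floor of 3 counts over the group, and for 1 to 3 counts a 95% exact Poisson interval of the ratio was computed.

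Ages were compared within each organ and assay with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust fitting, two-sided, TMM factors, Benjamini-Hochberg adjustment, adjusted p under 0.05). Transcripts entered when they passed edgeR's expression filter with a minimum count of 10 and a minimum total of 15. Translational efficiency, the ratio of ribosome-protected to RNA-seq counts, was tested as the interaction of age and assay over the 12 libraries of an organ. The difference between the organs in the effect of age was tested as the interaction of age and organ over the 12 libraries of an assay. Standard errors of log2 fold changes were derived from the F statistic, and CPM values are TMM-scaled. Single values such as depth were compared with two-sided exact permutation tests, which with 3 against 3 cannot give a p below 0.1.

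Sample titles carry the same animal code in both organs and both assays, and the design text calls the material matched. Libraries of the same animal deviated together from their age means: the correlations ran from 0.14 to 0.59 between brain RNA-seq and ribosome profiling and from 0.42 to 0.78 in liver, and each of the 6 animals matched itself best in both organs (exact permutation p = 0.0278 for each, the smallest that 36 pairings allow). Between brain and liver they ran from 0.0052 to 0.17 in RNA-seq and from -0.014 to 0.094 in ribosome profiling (exact permutation p = 0.0278 for each). A fit with the animal as a block was therefore set beside each interaction result. Replicate numbers of different ages mark different animals.

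The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), median-ratio and upper-quartile factors, other filters on low counts, the most abundant transcripts left out of library sizes, the spread estimated over all 12 libraries of an assay, a replicate or animal block, per-animal ratios tested with limma, a floor on expression for correlations, and each animal or library left out in turn. Later additions were removal of the trend with the length-like value, thinning to equal depth, an adjusted p under 0.10, and leaving out liver-enriched transcripts, alone or together with old animal 2. Liver-enriched transcripts in the brain comparisons were those at least 10 times higher in liver than in brain in young RNA-seq and at 1 CPM or more in liver, with 0.05 CPM added, a definition chosen after first inspection of the data. For the fall of organ-enriched transcripts with age, the sets for one assay were taken from the other assay by the same ratio, once from young animals and once from the mean of both ages, and a second definition used a ratio of at least 8 and 10 CPM.

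Each test was tried on simulated counts drawn from the real means and library sizes, with 200 transcripts changed. The changed transcripts had an average log2 CPM of at least 0, and the spread was the one edgeR estimated. A single run was made per setting, with no outlying animal and, unless stated, no animal effect. The shares may therefore be more favourable than in the real data. At a 4-fold change, 97% of changed transcripts were recovered in brain RNA-seq, 84.8% in brain ribosome profiling, 89.4% in liver RNA-seq, 95.5% in liver ribosome profiling, 84.8% in brain translational efficiency and 68.2% in liver translational efficiency. At a 2-fold change the shares were 79.1%, 56.7%, 61.2%, 44.8%, 41.8% and 7.46%. False calls made up 6.98%, 11%, 6.14%, 5.83%, 7.07% and 3.85% of calls in that order, so several lay above the nominal 5%. For the difference between organs, 74.2% of 4-fold changes were recovered in RNA-seq and 68.2% in ribosome profiling, with false shares of 2.53% and 7.41%. Where a shared animal effect was simulated in liver, the fit with the animal block recovered 71.6% of 2-fold changes in translational efficiency with 11.9% false calls, and the fit without it recovered 8.96%.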

Results

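Expression and translation were profiled in brain and liver of young (6 months) and old (24 months) rats, with RNA-seq for transcript abundance and ribosome profiling for ribosome-protected fragments of the same tissues. Each of the 8 groups held 3 animals, and every animal contributed all 4 kinds of library. The title of the series asks how ageing differs between organs. Mean total counts per library in brain RNA-seq were 15252294 ± 216682 in young and 16001969 ± 1641766 in old rats (SD, n = 3). In liver RNA-seq they were 19155608 ± 1729963 and 26644912 ± 1759702, with every old library deeper than every young one (exact permutation p = 0.1, the smallest possible with n = 3). Ribosome profiling libraries held 9393297 ± 3644325 and 9944593 ± 5250031 counts in young and old brain and 14866879 ± 2884930 and 12904572 ± 2342634 in liver. In liver, 10 transcripts took 26.74 ± 2.06% of RNA-seq counts in young and 32.81 ± 3.55% in old rats. The most abundant one, ENSRNOT00000003921, accounted for 9.504 ± 1.4% and 15.63 ± 3.96% (exact permutation p = 0.1, n = 3), and for 12.19 ± 2.14% and 16.35 ± 3.35% of liver ribosome-protected counts (exact permutation p = 0.2). The identifiers could not be paired with gene names, so transcripts are given by identifier and their functions are not stated.

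Transcripts typical of liver were present in the brain libraries at unequal levels. Of the 50 liver-enriched transcripts most abundant in liver, the median level in old animal 2 was 7.43 in brain RNA-seq and 8.17 in brain ribosome profiling, as log2(CPM + 0.5). The other brain RNA-seq libraries lay at -0.34, -0.32, -0.11 and -0.02, and at 1.77 in old animal 3. In brain ribosome profiling, young libraries lay at 0.21, 0.37 and 0.85, and those of old animals 1 and 3 at 3.98 and 3.68. Together these 50 transcripts reached 5.35% of their liver level in the RNA-seq library of old animal 2, against 0.685% to 1.09% in the other brain libraries, and 6.55% against 0.638% to 1.19% in ribosome profiling. Brain-enriched transcripts in the liver libraries held 1.99% to 2.53% of their brain level in young and 2.12% to 3.27% in old rats. The highest values, 3.27% in RNA-seq and 3.03% in ribosome profiling, were both in old animal 3. There, levels of the brain-enriched transcripts correlated with those in brain at only 0.113 and 0.193. The other liver libraries lay at 0.0722 to 0.104 and 0.176 to 0.212. For the liver-enriched transcripts in brain of old animal 2, the correlations with liver were 0.907 and 0.912. Enrichment in young animals selects transcripts that are low in young brain, and old libraries can carry a transcript past the count filter, so the tally in brain was made on transcripts enriched over both ages that passed the filter on the young libraries alone. Of these, 262 of 275 were higher and 13 lower in old brain RNA-seq, with a median log2 fold change of 0.57, and 214 of 231 were higher and 17 lower in ribosome profiling, with a median of 0.73. These transcripts are not independent replicates. In RNA-seq the 50 transcripts above lay at 7.43 in old animal 2 and at -0.02 in old animal 1. The tally therefore does not show a rise in every old animal.

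**Figure D1:**
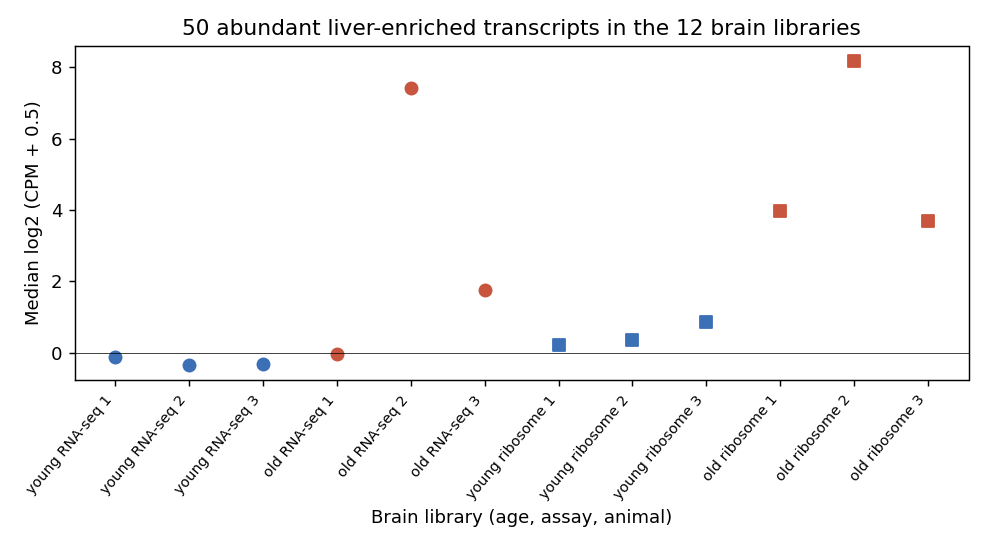
Median log2(CPM + 0.5) of the 50 liver-enriched transcripts most abundant in liver, in each of the 12 brain libraries (blue, 6 months; red, 24 months; circles, RNA-seq; squares, ribosome profiling; one point per library). Old animal 2 lies at 7.43 and 8.17, and the ribosome profiling libraries of old animals 1 and 3 lie at 3.98 and 3.68, above the young ones.

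In old brain, 66 transcripts changed in abundance. ENSRNOT00000000525 rose from 1.8 ± 0.225 to 6.88 ± 2.65 CPM (SD, n = 3; log2 fold change 1.93, SE 0.279, adjusted p = 0.0325), and ENSRNOT00000000180 rose from 1.45 ± 0.417 to 4.97 ± 1.65 CPM (log2 fold change 1.76, SE 0.305, adjusted p = 0.0432). ENSRNOT00000058665, an abundant transcript with 0 counts in every liver library, fell from 676 ± 57.2 to 447 ± 26.7 CPM (log2 fold change -0.60, SE 0.0679, adjusted p = 0.0142). ENSRNOT00000065181 fell from 82.8 ± 7.98 to 52.4 ± 6.84 CPM (log2 fold change -0.66, SE 0.102, adjusted p = 0.046). The rule for naming transcripts required that the 3 old and the 3 young libraries did not overlap, so their separation is no further support. In all, 44 transcripts rose and 22 fell among 13986 tested (edgeR, adjusted p under 0.05), with median log2 fold changes of 0.52 and -0.34, and liver-enriched transcripts made up 3 of the 44. DESeq2 called 294, and edgeR with the spread estimated over all 12 RNA-seq libraries called 0, with 801 at an unadjusted p under 0.05 and adjusted p of 0.135 to 0.998 for the transcripts named here. Of all tested transcripts 19.2% showed no overlap between the ages. Over the 10 splits of the animals into 3 and 3, a share of 10% is expected on average. Transcripts are not independent, so a single split can lie above 10% without an effect of age, and the share was not computed for other splits. At an unadjusted p under 0.05, age gave 1954 transcripts in edgeR. Young animal 1, old animal 1 and old animal 2 against the rest gave 1682. The count of 66 moved to 1128 without young animal 1, 2 without young animal 2, 1 without young animal 3, and 3, 8 and 10 without old animals 1, 2 and 3. It was 122 with liver-enriched transcripts left out, 63 of them among the 66, and 3 when old animal 2 was left out as well.

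Ribosome-protected counts of old brain changed for 232 transcripts. ENSRNOT00000029049 rose from 0.269 ± 0.4 to 4.21 ± 3.71 CPM (SD, n = 3; log2 fold change 3.88, SE 0.868, adjusted p = 0.0295). Its highest value, 8.49 CPM, was in old animal 2, and it is liver-enriched, with 72.5 ± 70.9 CPM in young liver RNA-seq and 1.41 ± 0.356 CPM in young brain RNA-seq. Its log2 fold change was 6.06 without young animal 3 and 2.79 without old animal 2 (adjusted p = 0.224), and its call was also lost without young animal 1 (adjusted p = 0.0982), young animal 2 (0.209) or old animal 1 (0.0844). ENSRNOT00000055513 rose from counts of 3, 0 and 1 to counts of 25, 17 and 11 (log2 fold change 3.89, SE 1.02, adjusted p = 0.0491), with 1 count over all 6 brain RNA-seq libraries. This value was 2.99 without old animal 1 (adjusted p = 0.318), and the call was lost in 10 of 18 alternatives. ENSRNOT00000012061 fell from 24.1 ± 3.5 to 11.7 ± 0.062 CPM (log2 fold change -1.02, SE 0.207, adjusted p = 0.0116), and ENSRNOT00000057735 fell from 24.4 ± 7.42 to 11.6 ± 3.13 CPM (log2 fold change -1.05, SE 0.25, adjusted p = 0.0364). Their calls were lost in 4 and 7 of 19 alternatives, in that order. Among 13570 transcripts tested, 107 rose and 125 fell (edgeR, adjusted p under 0.05), of which 29 rose and 3 fell at least 2-fold, and 17 of the rising ones were liver-enriched. DESeq2 called 390, and edgeR with the spread over all 12 ribosome profiling libraries called 13, 12 higher and 1 lower and 6 of them among the 232, with adjusted p of 0.2 to 0.717 for the transcripts named here. No overlap between ages was found for 19.4% of tested transcripts, where 10% is expected on average over splits of the animals. The trend of log2 CPM with the length-like value also separated the ages. Its Spearman's rho was 0.0243 to 0.0576 in young and -0.164 to -0.00393 in old libraries. The share therefore cannot be credited to age alone. The count of 232 was 33 without young animal 2, 47 without young animal 3, 57 without old animal 1 and 135 without old animal 3. With each of the 6 libraries left out in turn, that of old animal 2 included, it ranged from 33 to 321. The highest was without young animal 1.

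Changes in abundance and in ribosome-protected counts went the same way in brain for most called transcripts. Of 65 transcripts called in RNA-seq and tested in both assays, 62 had the same sign in ribosome profiling. Of 229 called in ribosome profiling, 194 had the same sign in RNA-seq. Both assays called 14 transcripts higher and 8 lower, where 0.34 and 0.21 would coincide in independent lists, and 0 in opposite directions. The lists are not independent, since both come from the same 6 animals, whose log2 fold changes correlated between the assays at 0.542 to 0.621 in the other splits of the animals. ENSRNOT00000000525 rose in both, with a ribosome profiling log2 fold change of 2.48 (adjusted p = 8.88e-06), and ENSRNOT00000065181 fell in both, with -0.75 (adjusted p = 0.00215). Across 13189 transcripts, which are not independent replicates, the log2 fold changes correlated at r = 0.697 (Spearman's rho 0.382). The correlation was 0.473 without liver-enriched transcripts, where the other splits gave 0.227 to 0.364. Over all transcripts it was 0.427 without old animal 2.

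**Figure D2:**
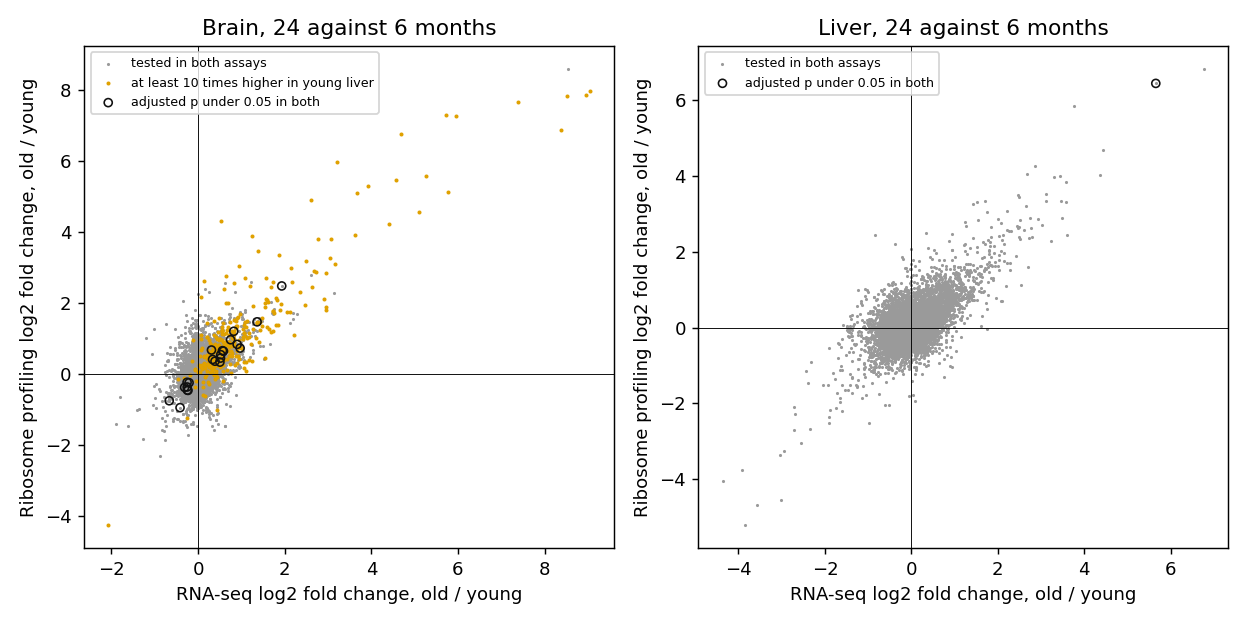
Log2 fold change of old against young in RNA-seq (x axis) and ribosome profiling (y axis) for each transcript tested in both, in brain (left) and liver (right). Open circles mark transcripts with an adjusted p under 0.05 in both assays (22 in brain, 1 in liver), and yellow points mark transcripts at least 10 times higher in young liver than in young brain, which fill the upper right of the brain panel.

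Translational efficiency in old brain changed for 12 of 14664 transcripts, 11 higher and 1 lower (edgeR interaction test, adjusted p under 0.05). ENSRNOT00000012258 had ribosome-protected counts of 1.64 ± 0.528 CPM in young and 5.97 ± 1.98 CPM in old brain (SD, n = 3), while its RNA-seq level was 32.8 ± 2.74 and 31.4 ± 1.14 CPM, so its efficiency rose by 1.82 on the log2 scale (SE 0.317, adjusted p = 0.0448). ENSRNOT00000051652 went from 1.73 ± 0.343 to 4.44 ± 0.771 CPM in ribosome profiling and from 21.1 ± 1.4 to 18.8 ± 1.89 CPM in RNA-seq (log2 change in efficiency 1.59, SE 0.273, adjusted p = 0.0448). ENSRNOT00000012061 was the transcript with lower efficiency (log2 change -1.18, SE 0.206, adjusted p = 0.0448), since its ribosome-protected counts fell and its RNA-seq level was 13.9 ± 0.612 CPM in young and 15.7 ± 1.63 CPM in old brain. With the animal as a block, 31 transcripts passed, 27 higher and 4 lower, and all 12 were among them, 0 of the 12 being liver-enriched. The 27 had a median length-like value of 141, against 415 over all tested. With the length trend removed the block gave 15 higher and 7 lower, and at equal depth 10 higher and 5 lower. The blocked count was 7 without young animal 2 and 15 without old animal 3. The count of 12 was 3 without young animal 1, 6 without old animal 2 and 0 without young animal 2, young animal 3, old animal 1 or old animal 3, where edgeR gave 760, 974, 927 and 809 transcripts at an unadjusted p under 0.05, against 1041 in the full fit. Under another scaling of the same fit the count was 4 with median-ratio factors and 0 with upper-quartile factors (1036 at an unadjusted p under 0.05), and the adjusted p of the transcripts named here was 0.0517 to 0.0541 and 0.0592 to 0.0701. By other tools on all animals, DESeq2 called 64, and limma-voom and limma on per-animal ratios each called 0, with 1086 and 1116 at an unadjusted p under 0.05.

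In old liver, ENSRNOT00000010238 rose from 0.35 ± 0.223 to 18.1 ± 4.81 CPM in RNA-seq (SD, n = 3; log2 fold change 5.66, SE 0.386, adjusted p = 0.0125), close to its level in brain, where it stood at 17.5 ± 2.28 and 16.8 ± 0.44 CPM in young and old animals. ENSRNOT00000004408 rose from 1.8 ± 0.232 to 10.3 ± 2.13 CPM (log2 fold change 2.51, SE 0.21, adjusted p = 0.0237). These were the 2 transcripts of 12198 with an adjusted p under 0.05 by edgeR, both higher in each old library than in each young one, and 0 fell. Many more passed looser thresholds: 2819 had an unadjusted p under 0.05, and 901 had an adjusted p under 0.10 (354 higher, 547 lower). Of tested transcripts 29.7% did not overlap between ages, where 10% is expected on average over splits of the animals. The trend of log2 CPM with the length-like value also separated the ages. Its Spearman's rho was 0.147 to 0.173 in young and -0.326 to -0.0596 in old libraries. These shares therefore cannot be credited to age alone. DESeq2 called 1060 and limma-voom 0. The RNA-seq counts of 66 in brain and 2 in liver do not rank the organs by their age effect. An adjusted p under 0.10 gave 243 in brain and 901 in liver, and DESeq2 gave 294 and 1060. Limma-voom kept the order, with 59 and 0. The count of 2 became 641 without young animal 1, 35 without old animal 3, and 0 without young animal 2, young animal 3 or old animal 1, where 1688, 1979 and 2140 had an unadjusted p under 0.05.

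Ribosome profiling of old liver showed the same rise of ENSRNOT00000010238, from 0.215 ± 0.278 to 17.1 ± 6.71 CPM (SD, n = 3; log2 fold change 6.44, SE 0.66, adjusted p = 0.0465), with young counts of 6, 0 and 2. Over 17 alternatives its log2 fold change ranged from 5.855 to 7.904, and the call was lost in 5 of them. ENSRNOT00000026303 rose from 2.1 ± 0.785 to 24.0 ± 4.75 CPM (log2 fold change 3.48, SE 0.284, adjusted p = 0.00346), and its RNA-seq level was 3.42 ± 1.74 CPM in young and 19 ± 1.65 CPM in old liver (log2 fold change 2.47, adjusted p = 0.0547). ENSRNOT00000004408 had a ribosome profiling log2 fold change of 2.33 (adjusted p = 0.0573), from 1.63 ± 0.506 to 8.13 ± 2.47 CPM. By edgeR, 2 of 11396 transcripts passed, both higher, and 0 fell, while 1390 had an unadjusted p under 0.05. DESeq2 called 226 and limma-voom 1. The share without overlap between ages was 18.7%, where 10% is expected on average over splits of the animals. As transcripts are not independent, the excess is not evidence of an age effect by itself. The count of 2 became 96 without young animal 1, 37 without old animal 3, 7 without old animal 2, 1 without young animal 3 and 0 without young animal 2, where 838 had an unadjusted p under 0.05.

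**Figure D3:**
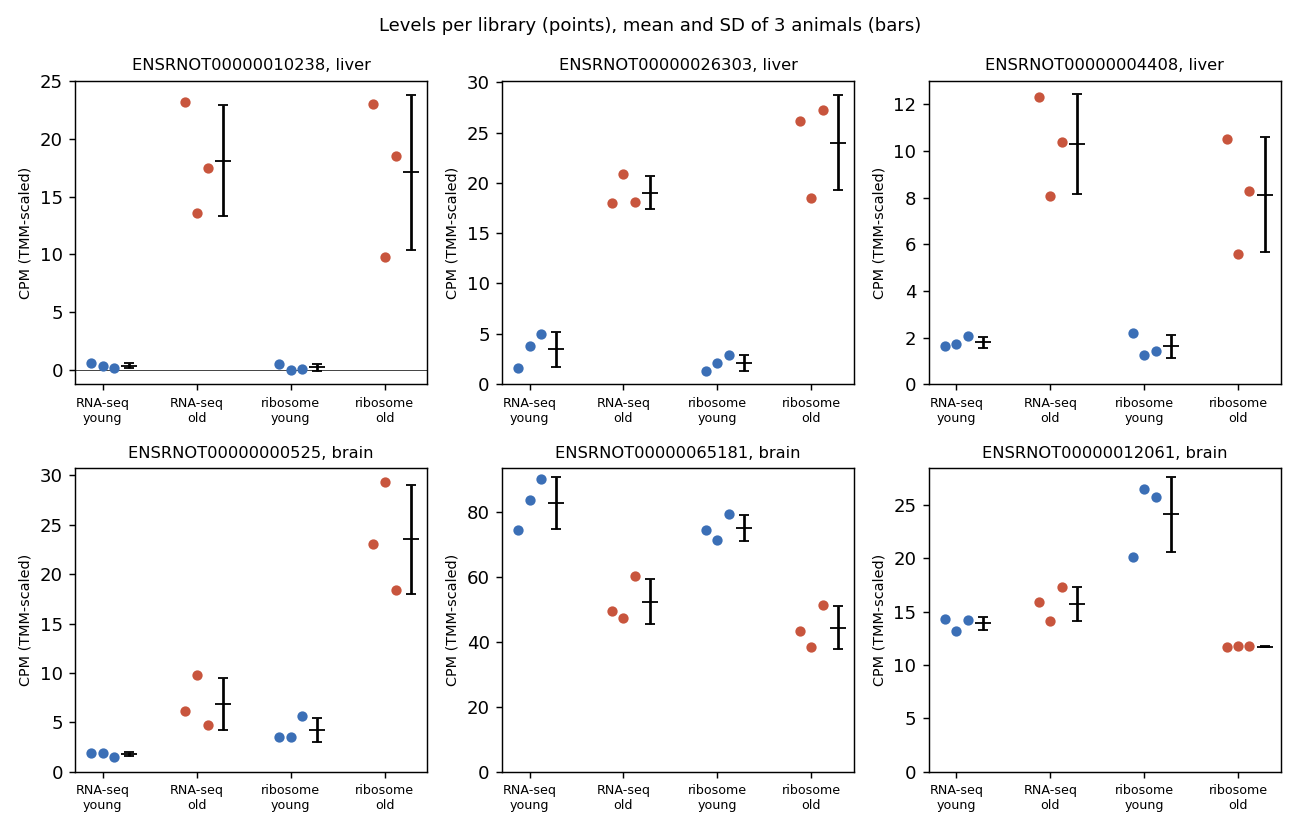
TMM-scaled CPM per library of 6 transcripts named in the text, in liver (top) and brain (bottom), for RNA-seq and ribosome profiling at 6 months (blue) and 24 months (red). Points are single animals and bars are mean and SD of n = 3; ENSRNOT00000010238 goes from 0.35 to 18.1 CPM in liver RNA-seq, and ENSRNOT00000012061 falls from 24.1 to 11.7 CPM in brain ribosome profiling with RNA-seq levels of 13.9 and 15.7 CPM.

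Across 11113 liver transcripts tested in both assays, the log2 fold changes of RNA-seq and ribosome profiling correlated at r = 0.623 (Spearman's rho 0.389; transcripts are not independent replicates). Both assays come from the same animals, and other splits of the animals gave 0.484 to 0.699. Of the 10 splits, age included, 4 were as high as age. ENSRNOT00000010238 was called in both assays, and ENSRNOT00000004408 and ENSRNOT00000026303 in one each, with the same sign in the other.

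Translational efficiency in old liver differed from young liver for 0 of 12462 transcripts by edgeR without the animal as a block, although 1254 had an unadjusted p under 0.05. DESeq2 called 121 and limma-voom 0. The edgeR fit with the animal as a block called 841 transcripts, 332 higher and 509 lower, with median log2 changes of 0.83 and -0.55. Of these 111 rose and 16 fell at least 2-fold. Limma on the ratio of each animal's ribosome profiling to its RNA-seq called 0, with 2550 at an unadjusted p under 0.05, so the 841 calls were not made by that test. The transcripts that rose had a median length-like value of 740 and those that fell 307, against 412 over all tested. Leaving out single animals moved the blocked count to 1740 without young animal 1, 43 without young animal 2, 185 without old animal 1, 357 without old animal 2 and 460 without old animal 3, and the unblocked count to 6 without young animal 1.

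Age effects on RNA abundance differed between the organs for single transcripts. ENSRNOT00000010238 rose in liver and was at 17.5 and 16.8 CPM in brain, and the difference between the effects was 5.71 on the log2 scale (SE 0.39, adjusted p = 0.000124). ENSRNOT00000033784 went from 0.103 ± 0.179 to 2.18 ± 1.22 CPM in liver and from 1.2 ± 0.12 to 0.61 ± 0.136 CPM in brain (SD, n = 3; difference 5.35, SE 1.0, adjusted p = 0.0381). Its young liver libraries held 0, 0 and 6 counts, and the difference was 10.1 without young animal 3 (adjusted p = 0.111) and 4.73 without young animal 2. ENSRNOT00000010634 had 5, 8 and 11 counts in the young liver libraries and 0 in all 3 old ones, at least 11.1-fold lower against a floor of 3 counts over the group, while brain held 47.9 ± 0.925 and 48.5 ± 0.95 CPM (adjusted p of the difference = 0.01). ENSRNOT00000012381 had 94 counts over the young and 3 over the old liver libraries, 43.6-fold lower with a 95% counting interval of 14.5 to 215, against 1.72 ± 0.801 and 1.13 ± 0.231 CPM in brain (fitted difference -4.63, SE 0.768, adjusted p = 0.0295). In all, 151 of 14762 transcripts differed, 52 with a higher and 99 with a lower age effect in liver than in brain. With the animal as a block 2 passed, 1 of them among the 151, and ENSRNOT00000010238 kept its call there, while the other transcripts named here had an adjusted p of 0.0798 to 0.11. The count of 151 became 280 with liver-enriched transcripts left out, 564 without young animal 1, 59 without old animal 3, and 1 without young animal 2, young animal 3 or old animal 1.

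In ribosome profiling the organs differed in the age effect for 2 of 14440 transcripts. ENSRNOT00000010238 had a difference of 6.64 on the log2 scale (SE 0.608, adjusted p = 0.00079), with 53.3 ± 2.92 and 45.9 ± 2.94 CPM in young and old brain (SD, n = 3). ENSRNOT00000009705 went from 2.19 ± 0.903 to 0.227 ± 0.0837 CPM in liver and from 630 ± 24.4 to 531 ± 9.69 CPM in brain (difference -3.07, SE 0.407, adjusted p = 0.0169). The transcript was lower in both organs, and its fall in brain was itself called (log2 fold change -0.24, edgeR adjusted p = 0.0311). In liver the log2 fold change was -3.25 (adjusted p = 0.0876), from counts of 13, 38 and 48 to counts of 2, 4 and 3. Its liver RNA-seq level moved from 2.01 ± 0.851 to 0.25 ± 0.11 CPM. By edgeR 1772 transcripts had an unadjusted p under 0.05, and DESeq2 called 382. With the animal as a block 4 passed, 1 of them among the 2 (adjusted p = 0.0352 for ENSRNOT00000010238 and 0.133 for ENSRNOT00000009705), with liver-enriched transcripts left out 10 passed, and single animals left out gave 21 without young animal 1, 91 without old animal 2, 34 without old animal 3, 1 without young animal 2 or old animal 1 and 0 without young animal 3, where 1301 had an unadjusted p under 0.05.

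Age effects correlated weakly between brain and liver. Across 11484 transcripts tested in both organs the RNA-seq log2 fold changes correlated at r = 0.12 (Spearman's rho 0.171), and across 10721 in ribosome profiling at r = 0.0214 (rho 0.0726). Other splits of the animals reached 0.193 in RNA-seq and 0.116 in ribosome profiling. Of the 10 splits, age included, 2 and 7 were as high as age. Of 52 transcripts called in brain RNA-seq and tested in liver, 37 had the same sign in liver and 0 were called there. Among all 11484 transcripts 55.6% had the same sign. Without liver-enriched transcripts the correlations were 0.221 and 0.146, where the other splits reached 0.219 and 0.0934. The RNA-seq correlation was 0.0663 without old animal 1 and 0.19 without old animal 2, and that of ribosome profiling was -0.0178 without young animal 2, -0.012 without young animal 3 and 0.0673 without old animal 2.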

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

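Chosen only after the result was seen were the splits for brain and liver RNA-seq and ribosome profiling, the liver transcripts in brain ribosome profiling, the test of a fault of one library, the values without liver-enriched transcripts, and all tests of the second split. The other tests in this part were written before their results were seen.

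The effect of age differed between liver and brain in a test of the difference itself for 151 transcripts in RNA-seq and 2 in ribosome profiling without the animal as a block. With the block 2 and 4 passed, and of the transcripts listed here only ENSRNOT00000010238 kept its call, in both assays. In RNA-seq the difference (liver minus brain, log2) was 5.71 for ENSRNOT00000010238, 5.35 for ENSRNOT00000033784, -6.64 for ENSRNOT00000010634 and -4.63 for ENSRNOT00000012381. The value for ENSRNOT00000033784 rests on young liver counts of 0, 0 and 6 and ranged from 4.73 to 10.1 over the alternatives, and that for ENSRNOT00000010634 is a fitted one that depends on the prior count, since its old liver libraries held 0 counts. In ribosome profiling the difference was 6.64 for ENSRNOT00000010238 and -3.07 for ENSRNOT00000009705. Old animal 2 entered these fits with liver transcripts in its brain libraries, and leaving liver-enriched transcripts out gave 280 and 10 calls.

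The 6 animals can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. Age gave 66 calls in brain RNA-seq against at most 2 in another split, 232 against 0 in brain ribosome profiling, 12 against 0 in brain translational efficiency (31 against 14 with the animal as a block), and 2 against 0 in liver RNA-seq. It gave 2 against 4 in liver ribosome profiling, 0 against 1 in liver translational efficiency (841 against 1 with the block), 151 against 3 in the difference between organs in RNA-seq and 2 against 4 in that difference in ribosome profiling. The number of splits with as many calls as age, age included, was 1 in brain RNA-seq, brain ribosome profiling, liver RNA-seq, both blocked fits, brain translational efficiency and the RNA-seq difference between organs. It was 2 in liver ribosome profiling and in the ribosome profiling difference, and 10 in liver translational efficiency without the block.

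Liver translational efficiency went from 0 calls to 841 in the edgeR fit with the animal as a block, while limma on per-animal ratios called 0. A trend with the length-like value between libraries may account for part of them: with that trend removed, 486 of the 841 were still called (57.8%), all 841 had the same direction, and their median absolute log2 change went from 0.622 to 0.537. In liver RNA-seq that trend separated the ages, at 0.147 to 0.173 in young and -0.326 to -0.0596 in old libraries (Spearman's rho). With all libraries thinned to equal depth, 627 were still called (74.6%), and the median of 0.622 became 0.603. All 840 transcripts tested after thinning kept their direction. Thinning removes counts and so lowers the power of the test, so the lost calls do not show that depth produced any part. Both shares lie between the bounds that were set beforehand for a whole cause and for none, so neither explanation is decided and both stay open. Age itself stays open as an untested explanation, and on simulated counts the blocked fit with a shared animal effect had 11.9% false calls.

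Old animal 2 stood apart from the other brain libraries. RNA from liver in its brain tissue is a candidate explanation: 50 abundant liver-enriched transcripts were higher by a median of 7.16 log2 units in its RNA-seq library than in the other 5 libraries, and by 6.68 in ribosome profiling, and their levels correlated with those in liver at 0.907 and 0.912. Leaving liver-enriched transcripts out brought its root mean square deviation in RNA-seq from 0.261 to 0.134, where the others lay between 0.137 and 0.191; in ribosome profiling it went from 0.377, beside 0.376 in young animal 2, to 0.248. A fault of one library preparation is argued against by a correlation of 0.59 between its deviations in the 2 assays, which use different protocols, although that value was 0.19 without liver-enriched transcripts. Where such RNA would have entered, and why old animals 1 and 3 also had raised levels in ribosome profiling, was not tested, and a biological difference of the old animals stays open.

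A split other than age ranked second in all 4 sets of libraries: young animal 1, old animal 1 and old animal 2 against the rest gave 1682 transcripts at an unadjusted p under 0.05 in brain RNA-seq, 661 in brain ribosome profiling, 1403 in liver RNA-seq and 1006 in liver ribosome profiling, where age gave 1954, 1911, 2819 and 1390. The same second split in both organs has a chance of 11.1% if splits rank at random. Depth separated the groups of that split in 1 of the 4 sets of libraries and the length trend in 2 of the 4. In liver RNA-seq both measures separated the ages, so no split that mixes ages could be separated there. The same held for the length trend in brain ribosome profiling. The length trend is therefore not argued against and stays open. The groups overlapped in depth in both brain assays, which argues against depth as the cause of the whole pattern. A state of the animals shared by both organs may contribute, since brain and liver RNA-seq libraries of the same animal deviated together more than in any other of the 36 pairings (exact share 0.0278, the smallest possible), also without liver-enriched transcripts (0.0278). Litter, cage or processing day stay open, as the labels name none, and so does chance, since that split itself gave 2, 0, 0 and 4 calls.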

How the results depend on the processing

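Removal of the length trend, thinning to equal depth, an adjusted p under 0.10, leaving out liver-enriched transcripts (alone or together with old animal 2) and the correlations over splits were chosen after the data were seen; all other settings were fixed before. The cause of a change was not tested unless stated. Counts follow the order brain RNA-seq (66), brain ribosome profiling (232), brain translational efficiency (12), liver RNA-seq (2), liver ribosome profiling (2), liver translational efficiency (0), RNA-seq difference between organs (151) and ribosome profiling difference (2). DESeq2 gave 294, 390, 64, 1060, 226, 121, 1118 and 382. An adjusted p under 0.10 gave 243, 406, 17, 901, 51, 7, 683 and 21. Leaving out one library or animal at a time gave 1 to 1128, 33 to 321, 0 to 6, 0 to 641, 0 to 96, 0 to 6, 1 to 564 and 0 to 91. Limma-voom gave 0 in brain translational efficiency, 0 in liver RNA-seq, 1 in liver ribosome profiling, 235 in the RNA-seq difference and 1 in the ribosome profiling difference. With no count filter, liver RNA-seq gave 143, liver ribosome profiling 53 and liver translational efficiency 1. In brain translational efficiency median-ratio factors gave 4, and upper-quartile factors and per-animal ratios with limma each gave 0, where 1036 and 1116 had an unadjusted p under 0.05. With the spread taken over all 12 libraries of an assay, brain RNA-seq gave 0 (801 at an unadjusted p under 0.05), brain ribosome profiling 13, liver RNA-seq 2254 and liver ribosome profiling 74. Thinned to equal depth liver RNA-seq gave 26, and with the length trend removed liver ribosome profiling gave 1. Without liver-enriched transcripts brain RNA-seq gave 122 and the differences between organs gave 280 and 10, and brain RNA-seq gave 3 when old animal 2 was left out too.

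With the animal as a block, brain translational efficiency gave 31 (27 higher and 4 lower), 22 with the length trend removed (15 and 7) and 15 at equal depth (10 and 5), liver translational efficiency 841 (637 with the length trend removed and 685 at equal depth), and the differences between organs 2 in RNA-seq and 4 in ribosome profiling. Animals of different age share only a replicate number: deviations of same-numbered libraries correlated between ages at 0.11, -0.0095 and 0.088 in brain RNA-seq, 0.0065, -0.043 and -0.053 in brain ribosome profiling, -0.037, -0.068 and 0.19 in liver RNA-seq and -0.041, -0.077 and 0.12 in liver ribosome profiling, and of the 3 numbers 2, 0, 1 and 1 matched themselves best. The replicate number as a block gave 287, 386, 79 and 5 calls in these comparisons.

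The correlation of age effects between RNA-seq and ribosome profiling ranged from 0.427 to 0.821 in brain and from 0.581 to 0.724 in liver with animals left out. Between brain and liver it ranged from 0.0663 to 0.19 in RNA-seq and was 0.221 without liver-enriched transcripts. In ribosome profiling it turned negative without young animal 2 (-0.0178), without young animal 3 (-0.012) and over transcripts with an average log2 CPM of at least 3 (-0.0042), with a highest value of 0.0673 when animals were left out, and was 0.146 without liver-enriched transcripts and 0.122 without old animal 2 as well. Over the 10 splits of the animals, brain RNA-seq and ribosome profiling correlated at 0.697 for age and at up to 0.621 otherwise, liver at 0.623 and up to 0.699, brain against liver RNA-seq at 0.12 and up to 0.193, and ribosome profiling at 0.0214 and up to 0.116. Without liver-enriched transcripts age gave more than any other split between brain and liver, 0.221 against up to 0.219 in RNA-seq and 0.146 against up to 0.0934 in ribosome profiling.

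Of the values of named transcripts under the alternatives other than the looser threshold, 224 stayed on the same side of the threshold, 116 kept their direction and lost the threshold, and 0 changed direction. ENSRNOT00000010238 in the RNA-seq difference between organs kept its call in all 15 alternatives (log2 difference 5.29 to 6.43, adjusted p 2.5e-35 to 0.0296). Gene lists, their set tests with fry and an estimated correlation, and the removal of mitochondrially encoded genes were not run, for lack of gene names. Depth limits most the transcripts with a few counts per library in one age, such as ENSRNOT00000055513 and ENSRNOT00000010634.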

Other observations

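All tests of organ-enriched transcripts were chosen only after the result was seen, as were the transcripts looked up in the other organ.

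Some of the transcripts named for one organ had the following values in the other. ENSRNOT00000000525, which rose in brain, was at 9.14 ± 0.129 CPM in young and 20.5 ± 5.13 CPM in old liver RNA-seq (SD, n = 3; log2 fold change 1.16, edgeR adjusted p = 0.0565) and had a log2 fold change of 0.98 in liver ribosome profiling (adjusted p = 0.176). ENSRNOT00000004408, which rose in liver RNA-seq, was at 4.21 ± 2.44 and 10.2 ± 2.87 CPM in brain RNA-seq (log2 fold change 1.27, adjusted p = 0.301) and at 3.3 ± 2.01 and 8.82 ± 4.09 CPM in brain ribosome profiling (log2 fold change 1.41, adjusted p = 0.114). ENSRNOT00000065181, which fell in both brain assays, was at 2.79 ± 0.909 and 8.4 ± 6.38 CPM in liver RNA-seq (log2 fold change 1.60, adjusted p = 0.156), and the difference between organs was 2.26 (adjusted p = 0.105). ENSRNOT00000000180, which rose in brain RNA-seq, had a log2 fold change of 0.30 in liver RNA-seq (adjusted p = 0.628), and ENSRNOT00000026303, which rose in liver ribosome profiling, had 0.43 in brain RNA-seq (adjusted p = 0.72). None of these values in the other organ passed the test.

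A hypothesis of a loss of organ-enriched expression with age was tested on transcripts at least 10 times higher in one organ over both ages, with the set for one assay taken from the other. In liver ribosome profiling, 472 of 738 liver-enriched transcripts were lower in old rats (64%, against 47% of the rest), and their median log2 fold change differed from that of the rest by -0.19, where another split of the animals reached 0.177 in size. In liver RNA-seq the difference was -0.0346, and another split reached 0.182. Brain-enriched transcripts lay at -0.0595 in brain RNA-seq and -0.0821 in brain ribosome profiling (other splits up to 0.054 and 0.0468), both smaller than the 0.1 set for the hypothesis but beyond every other split. Of them, 63.7% were lower in RNA-seq, against 47% of the rest, and 58.8% against 45.9% in ribosome profiling. Among single brain-enriched transcripts edgeR called 19 lower and 8 higher in RNA-seq, and 81 lower and 17 higher in ribosome profiling. Without old animal 2 and liver-enriched transcripts the brain differences were -0.0502 and -0.0665. Sets chosen on young animals alone gave -0.236 in liver ribosome profiling, -0.0422 in liver RNA-seq, -0.0591 in brain RNA-seq and -0.0822 in brain ribosome profiling (-0.262, -0.043, -0.0665 and -0.0983 in that order with the second definition), but such a choice itself favours a fall with age, so these values decide nothing. A small shift of organ-enriched transcripts to lower values may be present in both brain assays and in liver ribosome profiling (-0.0595, -0.0821 and -0.19), and only the last reached the size set for the hypothesis, by a narrow margin over the other splits and with 0 single liver-enriched transcripts called by edgeR. The 10 splits are too few for a share under 0.05, and the sets rest on the same animals.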
